A study of Mus musculus with 8 samples.

How the data were processed

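Total RNA from whole brain of 8 male mice, 4 per genotype, was hybridised to 8 single-channel Affymetrix Mouse430A_2 arrays, per the labels. The authors processed the arrays with RMA, per the submitters' processing notes, and its version was not given in the sources used here. The deposited table holds log2 values for 22690 probe sets. In the values themselves, 22689 probe sets had a median over the 8 arrays within 1e-05 of 0 and 1, the Maoa probe set 1428667_at, did not. Thus all but that 1 had been centred on their own median, a step that no label records. Centring removes the level of expression, and differences between arrays remain. Scanner files, scan dates and slide batches were not used here.

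The 64 control probe sets were left out of the tests and 22626 were tested, with no filter. Gene symbols came from the platform annotation and were updated by Entrez gene number to the RefSeq annotation of assembly GRCm38.p6, which was used for names and for the order of neighbouring genes only. Of the tested probe sets, 20380 had 1 symbol, 691 had several and 1555 had none or were not listed. The gene number matched for 20351 of those with 1 symbol, and no symbol changed. They stood for 12393 genes.

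The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the deposited log2 values, no covariate, two-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Sirt1 and Maoa were also compared by an exact permutation test over 70 arrangements. Gene lists, 22 of pathways and 20 of cell type or region markers with at least 5 measured genes each, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over all 42. The design had named the probe set with the highest mean as the value of a gene. On centred values that choice has no link to brightness, so the mean of a gene's probe sets was used instead and the original choice was run as an alternative. For list members the text gives this mean. Figures were drawn with matplotlib 3.10.9.

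The groups, tests, lists, most alternatives and the rule for named genes were set before the data were examined. The rule took Sirt1, Maoa and Nhlh2, then the 12 genes that rose and the 12 that fell with the largest change among called probe sets with 1 symbol. Where fewer passed, it was filled up to 12 with the smallest p among genes whose genotypes did not overlap. For a described list it took up to 4 members with the smallest p. Applying the rule to the fit without BSKO 2, and naming list members called there, was decided after the values were seen. One marker had first been matched to another gene through a shared synonym. After this was corrected, the hypothalamic list no longer passed the threshold.

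The alternatives were quantile normalization, centring of each array, leaving out probe sets that can cross-hybridise, eBayes with trend and robust settings, array weights, a replicate block, leaving out each array, a threshold of 0.10, a minimum fold of 1.2, 1 value per gene, an estimated correlation and fry. A filter on dim probe sets was not run, because centred values carry no brightness. Fits with replicates 1 and 2 against 3 and 4 as a term, with the striatal marker median as a covariate (8 arrays, and without BSKO 2), and with the probe set of the highest mean were added after seeing the data.

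The scripts were tested on simulated data with 200 changed probe sets among 22626, with each value drawn independently. With 8 arrays they recovered 15% of changes of 1.5-fold, 61.5% of 2-fold changes and 87.5% of 4-fold changes. With 7 arrays, without BSKO 2, they recovered 50.5%, 83.5% and 97%. False calls were 3.23%, 3.15% and 5.91% of all calls with 8 arrays, and 10.6%, 5.11% and 10.2% with 7, in 1 simulation of each.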

Results

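Gene expression was measured in whole brain of male C57/B6 mice aged 3 months that lacked SIRT1, an NAD-dependent protein deacetylase, in the brain (BSKO), and of their wild-type littermates (WT). Each genotype had 4 biological replicates, and each RNA sample was hybridised to its own single-channel Affymetrix Mouse430A_2 array. The number of arrays limits the precision. The deposited values are log2 values that lie around 0 for each probe set, so they give differences between arrays and no level of expression. Over the 22626 tested probe sets the SD of these values was 0.150 to 0.220 on the 4 WT arrays. It was 0.222 on BSKO 1, 0.831 on BSKO 2, 0.314 on BSKO 3 and 0.228 on BSKO 4. On BSKO 2 the 5' probe set for beta-actin lay -2.44 from the 3' one on the log2 scale, against -0.104 to 0.489 on the other 7 arrays. The same difference for Gapdh was -2.43 on BSKO 2 and -0.0749 to 0.0949 on the others. Results are therefore given with all 8 arrays and again without BSKO 2.

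**Figure D1:**
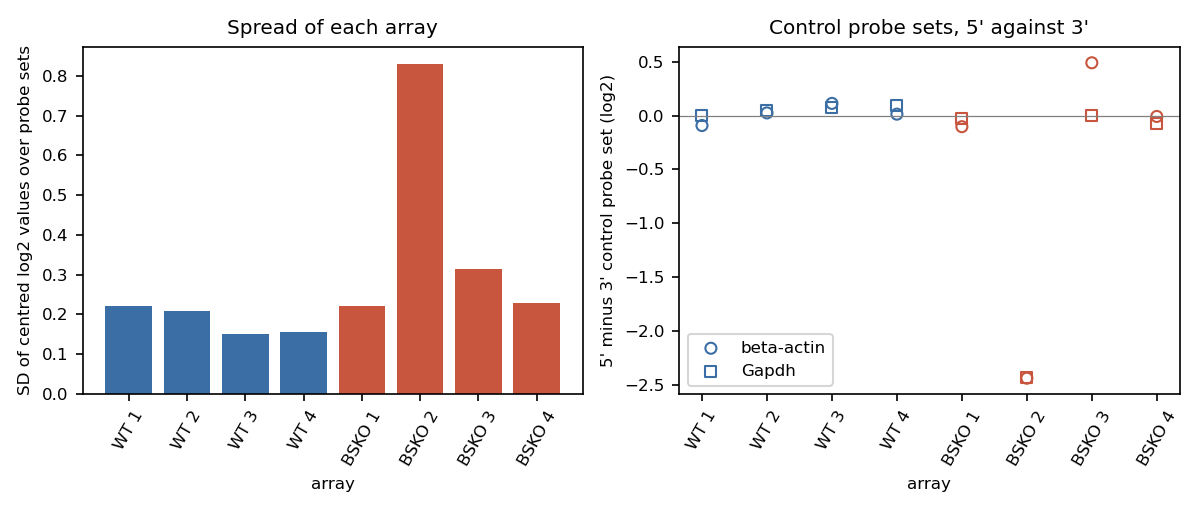
Left, the SD of the centred log2 values over 22626 probe sets on each array, with WT in blue and BSKO in red. Right, the log2 difference between the 5' and 3' control probe sets for beta-actin (circles) and Gapdh (squares) on each array, where BSKO 2 lies at -2.44 and -2.43.

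The knocked-out gene was examined first. Sirt1, measured by probe set 1418640_at, had a mean of 0.09 ± 0.14 (SD, n = 4) in WT and -0.41 ± 0.71 in BSKO, a difference of -0.50 (SE 0.31) on the log2 scale. The difference was within the spread between replicates (adjusted p = 0.549 by limma with Benjamini-Hochberg adjustment, and p = 0.114 by a two-sided exact permutation test over 70 arrangements). BSKO 2 carried most of it: without this array the difference was -0.15 (adjusted p = 0.428, exact permutation p = 0.257), where the adjusted p lay between 0.298 and 0.770 over all alternatives. The sources used here do not give the deleted part of Sirt1 or the part this probe set covers, so its signal neither checks nor contradicts the genotype labels.

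In the deposited values Maoa, which encodes the monoamine oxidase that breaks down serotonin and noradrenaline, was lower on every BSKO array than on every WT array. Its probe set 1428667_at had a mean of 0.01 ± 0.01 (SD, n = 4) in WT and -0.42 ± 0.33 in BSKO, a difference of -0.44 (SE 0.16), or 1.35-fold lower. Its value on BSKO 1 (-0.42414) equals the mean of the BSKO group, and the difference was unchanged without BSKO 1 (-0.4351). This is also the 1 probe set not centred on its median. Centred like the others, with its other values unchanged, it would have BSKO 1 at or above 0.0055, above WT 4. The complete separation rests on this BSKO 1 value, whose origin was not tested. The exact permutation p was 0.0286, the smallest that 4 against 4 arrays allow, and Maoa did not pass the test over all probe sets (limma adjusted p = 0.403). That permutation p needs BSKO 1 below every WT array, so it rests on the same value and is no separate support. Without BSKO 2 the difference was -0.28 (limma adjusted p = 0.121), with the same BSKO 1 value included. Nhlh2, a transcription factor gene of hypothalamic neurons, was not analysed here, since no probe set carries it as its single gene symbol.

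Krt2, Kctd4, Ptgs2 and Tcim fell in BSKO brain and Ighm rose, each on 1 called probe set. Krt2, an epidermal type II keratin, had the largest change among the called probe sets, from 1.41 ± 0.32 (SD, n = 4) in WT to -1.17 ± 0.19 in BSKO, which is 5.97-fold lower (log2 difference -2.58, SE 0.17, adjusted p = 0.00497). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, was 2.41-fold lower (log2 difference -1.27, adjusted p = 0.0208), Kctd4 2.19-fold lower (-1.13, adjusted p = 0.0108) and Tcim 2.47-fold lower (-1.30, adjusted p = 0.0455). Ighm, the constant region of the immunoglobulin mu heavy chain, was 3.71-fold higher on probe set 1427351_s_at (log2 difference 1.89, SE 0.18, adjusted p = 0.0208). Its probe set 1427329_a_at differed by 1.54 and missed the threshold (adjusted p = 0.102). As the mean of all probe sets of a gene, neither Ighm (11 probe sets, 0.62, adjusted p = 0.0977) nor Ptgs2 (2 probe sets, -1.10, adjusted p = 0.0732) passed, while Krt2, Kctd4 and Tcim, with 1 probe set each, did. The others of the 9 genes called this way, all lower in BSKO, were Apaf1 (-1.08), Neurod1 (-1.31), B130024G19Rik, Cyp26a1, Fibin and Nabp1, each with an adjusted p of 0.0495. Probe set 1418271_at, which has no gene name here, fell by 1.35, and 1419426_s_at, which is listed under several gene symbols, rose by 1.56. These 7 probe sets, 2 higher and 5 lower in BSKO, were the ones with an adjusted p under 0.05 among 22626 (limma with Benjamini-Hochberg adjustment). At an unadjusted p under 0.05 there were 2440. For each of the 7, all 4 BSKO arrays lay on one side of all 4 WT arrays. The groups did not overlap for 2790 probe sets (1282 higher, 1508 lower), or 12.3%, where chance gives 2.86% if every arrangement of the arrays is equally likely. Probe sets vary together across these arrays, so the gap between these shares is not a test of the genotype. None of the 7 was called without WT 4, 1 without WT 2 or WT 3, 2 without WT 1 or BSKO 3, 5 without BSKO 1 or BSKO 4, and all 7 without BSKO 2, always in the same direction. None was called with the replicate number as a block, where the log2 differences are identical (median size 1.35) and the median SE went from 0.147 to 0.132. The block fits more terms to the same arrays and leaves fewer residual degrees of freedom, which raises p for a given difference and SE. None was called with the median of the striatal markers as a covariate either, where all 7 differences kept their direction, with sizes between those of Tcim (-0.97) and Krt2 (-2.40), and the median SE was 0.198. At an unadjusted p under 0.05 the fit without WT 4 had 1576 probe sets.

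**Figure D2:**
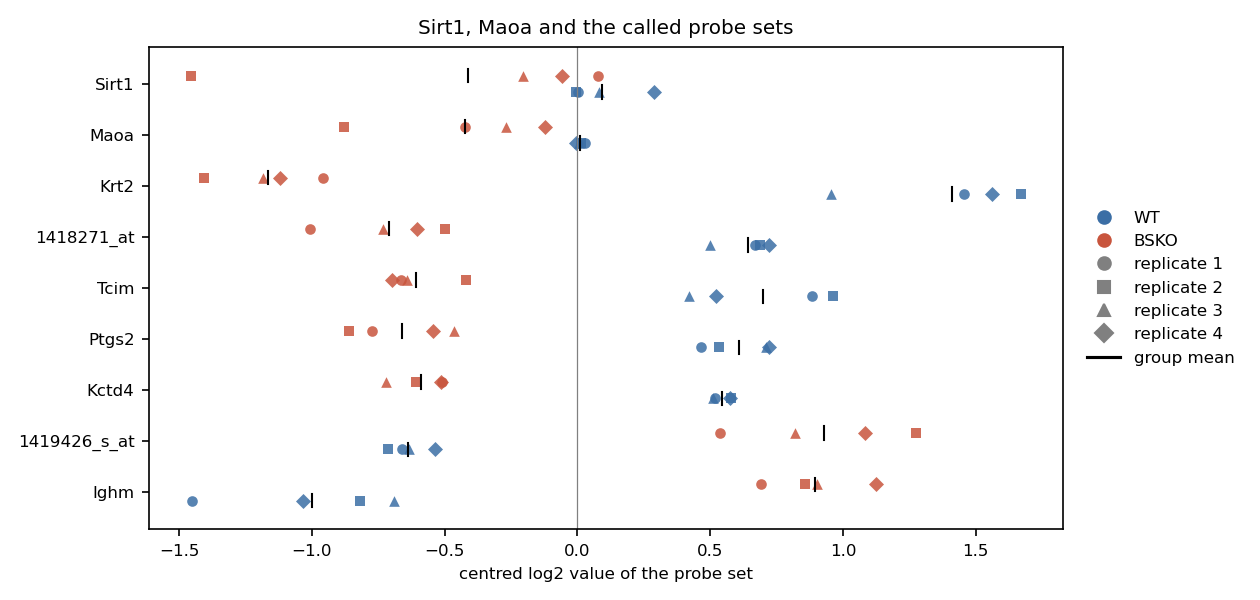
Centred log2 value of the Sirt1 and Maoa probe sets and of the 7 called probe sets on each array, with WT in blue, BSKO in red, marker shape for the replicate number and a black line for the group mean. The groups are separate for Maoa and the called probe sets, and overlap for Sirt1, where BSKO 2 lies farthest to the left. The Maoa value on BSKO 1 equals the mean of its group, and the separation rests on it.

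Further genes separated the genotypes completely and missed the threshold over all probe sets, and their differences are given as values. On the lower side in BSKO were Bdnf, a neurotrophin (-0.95, SE 0.12), Nr2f2, a nuclear receptor (-1.15), the long non-coding RNA gene B130024G19Rik (-0.93), Ccn3, a secreted matricellular protein (-1.83), Cyp26a1, which degrades retinoic acid (-1.54), Fibin (-1.40), Syt17 (-1.03) and Nabp1 (-0.90), each with an adjusted p of 0.0652. On the higher side were Rspo1, an activator of Wnt signalling (1.70, adjusted p = 0.0654), Prss3 (0.86), Foxo1, a forkhead transcription factor whose protein is a known SIRT1 substrate (0.65, adjusted p = 0.0760), Tbc1d8 (1.10), Igfbp4 (0.80), Spint1 (1.11), Kif17, a kinesin (1.02), Abhd11os (1.21), Sphk2, a sphingosine kinase (0.79), Pard3 (0.57) and Rgs11 (0.80), with adjusted p values of up to 0.103. All 19 passed without BSKO 2 (adjusted p = 0.0129 to 0.0404), after quantile normalization and with array weights, where BSKO 2 had a weight of 0.0456. In that last fit BSKO 4 carried most of the weight of its group (3.69). As the 19 were picked from these data for a small p, these fits are no independent support. With trend and robust settings 16 passed, and with replicates 1 and 2 against 3 and 4 as a term 10 did, the 8 lower ones with Tbc1d8 and Sphk2. Without BSKO 4, 1 passed. None passed when any other single array was left out, with each array centred, or with the replicate number as a block or the striatal covariate. Without cross-hybridising probe sets 16 were tested and none passed. In each of the other fits named here all 19 kept their direction. Their median size was 1.02 with 8 arrays (median SE 0.139), the same with the block (SE 0.140) and 0.935 with the covariate (SE 0.199), where 7 of the 19, Ccn3 (-1.99) and Cyp26a1 (-1.92) among them, were larger.

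Without BSKO 2, 369 probe sets passed the same threshold, 112 higher and 257 lower in BSKO, and they included all 7 above. The left-out array differed from the WT mean in the same direction for 300 of the 369 (81.3%). On simulated data 5.11% to 10.6% of the calls of this fit were false. Those data had no correlation between genes and no structure shared by arrays, so this does not estimate the false share of the 369. The median SE of a log2 difference was 0.163 with 8 arrays and 0.0982 without BSKO 2. The changes that follow are for probe sets with 1 gene symbol, each gene on its called probe set with the smallest p. In this fit of 4 WT and 3 BSKO arrays the largest decreases after Krt2 (-2.50) were those of Tspan8 (-2.11), Mpzl2 (-2.00), the thyrotropin-releasing hormone receptor gene Trhr (-1.77), the fatty acid transporter Cd36 (-1.66), the neuropeptide Y receptor gene Npy2r (-1.63), Ccn3 (-1.54, and -1.65 on the probe set of the value given with 8 arrays), Mndal (-1.49), the inducible heat shock gene Hspa1b (-1.49, adjusted p = 0.00618), Cyp26a1 (-1.47), Fibin (-1.40) and Pcdh20 (-1.40). The largest increases were those of Phex (2.02), Trbv1 (1.92), Ighm (1.79, and 1.90 on the probe set called with 8 arrays), Krt80 (1.49), Rspo1 (1.48), Foxp1 (1.43), Ryr1 (1.16), Blnk, a B cell adaptor (1.13), Tbc1d8 (1.11), Abhd11os (1.09), Cdcp1 (1.08) and Foxp2 (1.05). With BSKO 2 included, the genotypes overlapped for Cd36, Hspa1b, Phex and Foxp2. On that array Cd36 (0.87) and Hspa1b (0.37) lay above every WT array and Foxp2 (-0.85) below, opposite to their changes.

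At a preset inter-gene correlation, and not at an estimated one, markers of striatal projection neurons were called as higher in BSKO as a list. Markers of meninges and fibroblasts, of dentate gyrus granule neurons, of monoaminergic neurons and of astrocytes were called as lower in the same way. The list of circadian clock genes was also called as higher, and that of heat shock and unfolded protein response genes as lower. Of 42 gene lists fixed beforehand, these 7 passed an adjusted p of 0.05 by camera with a preset inter-gene correlation of 0.01. None passed with an estimated correlation, where the lowest adjusted p was 0.302 and 4 lists had an unadjusted p under 0.05. The rotation test fry, which does not compare a list with other genes, called the circadian list alone (adjusted p = 0.0414). No list held a member that passed over all genes with 8 arrays, apart from Neurod1, a neuronal transcription factor gene of the cerebellar list (-1.31 as the mean of its probe sets, adjusted p = 0.0495).

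The 8 measured striatal markers had a median log2 difference of 1.57 (adjusted p = 1.38e-05, and adjusted p = 0.577 with an estimated correlation). All 8 were higher in BSKO when adjusted over the list alone and none over all genes. The dopamine receptor gene Drd2 differed by 1.79 (SE 0.36), Rgs9 by 1.54, the phosphodiesterase gene Pde10a by 1.67 and the opioid precursor gene Pdyn by 1.61. The median of the list on each array was -1.79 on WT 1, -1.70 on WT 2, -0.03 on WT 3 and -0.09 on WT 4, against 0.10, 0.00, 1.12 and 1.06 on BSKO 1 to 4. Thus the WT arrays spanned 1.76, more than the difference of 1.47 between the genotype means. The difference was 1.79 within replicates 1 and 2 and 1.15 within replicates 3 and 4.

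WT 1 and WT 2 also stood apart from WT 3 and WT 4 for the meningeal, dentate gyrus and monoaminergic lists, which were called as lower, but not for the astrocyte list. The 9 meningeal and fibroblast genes had a median difference of -0.75 (adjusted p = 6.32e-07, and adjusted p = 0.366 with an estimated correlation), with 7 lower when adjusted over the list alone and none over all genes. Among them were the matrix proteoglycan genes Ogn (-1.54, SE 0.24), Lum (-0.91), Dcn (-1.79) and Fmod (-1.06). The list median was 0.70 and 0.80 on WT 1 and WT 2, 0.13 and 0.01 on WT 3 and WT 4, and -0.51 to -0.22 in BSKO. The 6 dentate gyrus markers had a median of -0.65 (adjusted p = 0.000399, and adjusted p = 0.309 with an estimated correlation), with Lct (-1.18) and Trpc6 (-0.59) lower when adjusted over the list alone. Their list median was 0.69 and 0.75 on WT 1 and WT 2 and 0.08 and 0.04 on WT 3 and WT 4. The 9 markers of monoaminergic neurons had a median of -0.77 (adjusted p = 0.0263, and adjusted p = 0.630 with an estimated correlation), none passed over the list alone, and the call was lost in several fits. The median stayed as large without BSKO 2 (-0.77, adjusted p = 0.122), without BSKO 1 (-0.85, 0.0587) and with trend and robust settings (-0.77, 0.162). It was smaller without WT 1 (-0.39, 0.0930), WT 2 (-0.43, 0.0720) or BSKO 3 (-0.46, 0.134), after quantile normalization (-0.45, 0.155) and with array weights (-0.38, 0.412). With the striatal median as a covariate it turned to 0.066 with 8 arrays and to 0.36 without BSKO 2. The dopamine transporter gene Slc6a3 differed by -3.87, with 2.02 and 2.08 on WT 1 and WT 2, 0.00 on WT 3 and WT 4, and -3.19, -4.41, -4.73 and 0.96 on BSKO 1 to 4. The 12 astrocyte genes had a median of -0.20 (adjusted p = 0.0146, and adjusted p = 0.577 with an estimated correlation), with the intermediate filament gene Gfap (-0.63, SE 0.14) lower when adjusted over the list alone. The list median was 0.09, 0.10, 0.07 and 0.01 on WT 1 to 4. Without BSKO 2 the astrocyte list was not called (median -0.12, adjusted p = 0.0729). With the striatal median as a covariate, which removes the striatal list by construction, the meningeal (median -0.57) and astrocyte (-0.27) lists were called with 8 arrays. Neither was called when BSKO 2 was left out as well (median -0.32, adjusted p = 0.133, and -0.13, adjusted p = 0.177). The heat shock list was called in the second of these fits (-0.09, adjusted p = 0.0285) and not in the first, and the dentate gyrus, monoaminergic and circadian lists in neither.

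**Figure D3:**
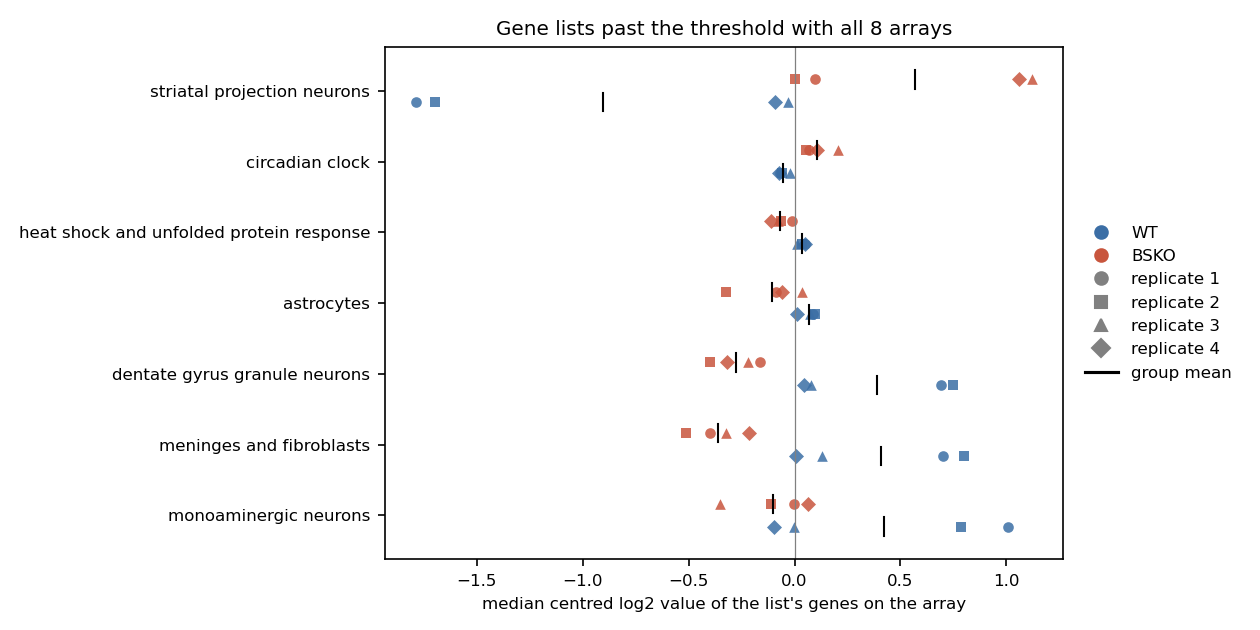
Median centred log2 value of the genes of each called list on each array, with WT in blue, BSKO in red, marker shape for the replicate number and a black line for the group mean. Replicates 1 and 2 lie apart from 3 and 4 among the WT arrays for the striatal, dentate gyrus, meningeal and monoaminergic lists.

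Of 17 circadian clock genes, 15 were higher in BSKO, with a median difference of 0.20 (adjusted p = 0.00652, and adjusted p = 0.302 with an estimated correlation). The output gene Dbp (0.63, SE 0.13) and the period gene Per1 (0.35, SE 0.09) were higher when adjusted over the list alone. Without BSKO 2 both rose over all genes as well (adjusted p = 0.0497 for each), and without BSKO 3 the list missed the threshold (adjusted p = 0.0589). Of 19 heat shock and unfolded protein response genes, 14 were lower in BSKO, with a median of -0.17 (adjusted p = 0.0118, and adjusted p = 0.302 with an estimated correlation). Hspa1a (-0.92, SE 0.20), which encodes an inducible HSP70, was lower when adjusted over the list alone, while Ddit3, a stress-induced transcription factor gene, differed by 0.42. With the probe set of the highest mean as the value of each gene, the heat shock list had a median of -0.03 and was not called (adjusted p = 0.0667). On centred values that choice favours probe sets whose values reach further up than down, so it is not a neutral check. Hspa1b fell without BSKO 2 (-1.33 as the mean of its probe sets, adjusted p = 0.00167). On BSKO 2 its probe set 1427126_at was 0.37, above every WT array.

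The remaining 35 lists did not pass, with adjusted p values from 0.0639 to 0.893. For 9 of them the median, the mean and the direction of the test differed in sign. The 15 genes of monoamine synthesis, transport and breakdown had a median of -0.17 (adjusted p = 0.0720, and adjusted p = 0.630 with an estimated correlation), and none passed over the list alone. They include Maoa, whose value on BSKO 1 equals the mean of its group. This list did pass without WT 3 (adjusted p = 0.0203), WT 4 (0.0237) or BSKO 4 (0.0202), with the replicate number as a block (0.0429), with replicates 1 and 2 against 3 and 4 as a term (0.043), and with the probe set of the highest mean per gene (0.0139). Without BSKO 2, Pnmt, which makes adrenaline, rose within that list (0.44, adjusted p = 0.0250). The 18 receptor genes for serotonin, dopamine and noradrenaline had a median of 0.09 (adjusted p = 0.819). Without BSKO 2 the serotonin receptor genes Htr2c (-0.89, adjusted p = 0.0281), Htr3a (-0.84, adjusted p = 0.0125) and Htr1a (-0.59, adjusted p = 0.0474) fell. On BSKO 2 itself Htr2c was -2.02, while Htr3a (0.027) and Htr1a (0.042) lay among the WT arrays. Bdnf (-0.73, adjusted p = 0.0232), as the mean of its probe sets, and the immediate early gene Jun (-0.70, adjusted p = 0.0300) also fell without BSKO 2.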

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

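The tests of RNA quality, of array spread, of the striatal list as a whole, of the striatal share and of gene list splits without BSKO 2 were chosen after the results were seen, as were the fits with replicates 3 and 4 as a term. The other tests were set before their results were seen.

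The spread of values on BSKO 2 was far from that of the other BSKO arrays, with an SD of 0.831 against 0.222 to 0.314. Its 5' against 3' control differences, which no comparison uses, were -2.44 for beta-actin (-0.104 to 0.489 on the other arrays) and -2.43 for Gapdh (-0.0749 to 0.0949). B130024G19Rik was lower on BSKO 2 (-0.666) than on the other BSKO arrays (-0.367 to -0.326). Of 74 groups of 4 arrays tested for a sample far from the others, 2 had one, where chance gives about 3.7.

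For BSKO 2, degraded RNA or target with a 3' bias is a candidate explanation, since the value of -2.44 lies below the other 7 arrays by more than their whole range. The genotype as the whole cause of the low 5' signal is argued against by the other BSKO arrays, where the lowest difference was -0.104 for beta-actin and -0.0749 for Gapdh. A small effect of the genotype stays open, since 1 of these 3 arrays for beta-actin and 2 for Gapdh lay below every WT array (lowest -0.0929 and -0.00186). For the wide spread itself the genotype as the whole cause is argued against by the same arrays, whose SD was at most 0.314, while BSKO 2 lay above that by more than the range of 0.164 among the other 7 arrays. A smaller effect of the genotype on the spread of every BSKO array stays open: all 3 others had an SD above every WT array, but the margin was 0.222 against 0.220.

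For the called probe sets, no other split of the 8 arrays gave as many: 1 of 35 splits, the real one, had 7, and the highest other had 0. Without BSKO 2 it was again 1 of 35, with 369 against 14. Chance alone is less likely but not excluded in either fit. The real split cannot do better than 1 of 35, and the test takes every arrangement of the arrays as equally likely. The split with 14 set replicates 3 and 4 of both genotypes against the rest, and with those replicates as a term the counts were 84 with 8 arrays and 744 without BSKO 2. A segment carried along with the targeted Sirt1 locus cannot be told apart from no such effect: 9 of 166 probe sets (5.42%) of the 100 nearest genes had an unadjusted p under 0.01, against 3.09% elsewhere (Fisher's exact test, one-sided p = 0.0747), and 8.43% against 7.77% without BSKO 2. Litter and rearing of the animals were not tested.

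For the gene lists chance cannot be excluded: 9 of 35 splits of the 8 arrays called as many as the real 7, up to 12, and without BSKO 2 it was 24 of 35 with the real 5 and up to 14, which points to a structure of the arrays beside the genotype. Unequal dissection may contribute, since 3 of the 11 region or attached-tissue lists passed. For the striatal list the genotype as the whole cause is argued against by a range of 1.76 among WT arrays, above the genotype difference of 1.47, and handling of replicates 1 and 2 apart from 3 and 4 as the whole cause by a difference of at least 1.15 within each pair of replicates. A striatal share as the cause of the 257 lower probe sets cannot be told apart from other causes. With the striatal median as a covariate they kept 92.3% of their log2 change (median, quartiles 78 and 108). However, they had been called for a small spread within each genotype, while the striatal median spans 1.76 among WT arrays, so a high share follows from the way they were chosen. The 257 probe sets with the lowest log2 difference whatever their spread, 108 of them the same, kept 73.4% (quartiles 38.9 and 102). Of the 257 called, 1 was still called with the covariate: their median SE went from 0.0979 to 0.137 and their median change from -0.67 to -0.61.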

How the results depend on the processing

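The fits with replicates 1 and 2 against 3 and 4 as a term, with the striatal covariate and with the probe set of the highest mean were chosen after seeing the data. The count of 7 called probe sets (2 higher, 5 lower) became 678 (224, 454) after quantile normalization, 108 (28, 80) with trend and robust settings, 2617 (1297, 1320) with array weights, which gave BSKO 2 a weight of 0.0456, 66 (10, 56) at a threshold of 0.10, 3 (1, 2) with a minimum fold of 1.2, 4 (0, 4) without cross-hybridising probe sets, and 9 (0, 9) with 1 value per gene. Without cross-hybridising probe sets 5 of the 7 were tested. Both higher ones, the Ighm probe set and 1419426_s_at, were left out by that filter, and Tcim was tested and missed the threshold (adjusted p = 0.0557). Leaving out 1 array gave 0 to 369 (0 to 112 higher, 0 to 257 lower), from without WT 4 to without BSKO 2. With replicates 1 and 2 against 3 and 4 as a term it was 84 (42, 42), and 744 (301, 443) without BSKO 2 as well. With the striatal covariate limma called 0 (0, 0) with 8 arrays, with 1833 at an unadjusted p under 0.05, and 5 (0, 5) when BSKO 2 was left out as well. The covariate itself differed by 1.47 between the genotypes. The cause was not tested except for fewer probe sets or arrays. Under the replicate block, which leaves fewer residual degrees of freedom, limma called 0 (0 higher, 0 lower), with 2121 at an unadjusted p under 0.05. The numbers were not seen to pair single arrays. Same-numbered arrays correlated at 0.0562 to 0.14 in their deviations, and for 3 of 8 arrays the best match in the other genotype had their own number. Between genotypes these correlations were all positive within replicates 1 and 2 or within 3 and 4. They were all negative across these pairs of replicates. Deviations from a group mean sum to 0 within each genotype, so negative signs partly follow from the positive ones. The signs went with the pairs of replicates in both genotypes, but the correlations were small (-0.147 to 0.165). The wide spread of BSKO 2 enters the deviations of all BSKO arrays, which makes the match by number a weak test. The count of 7 called lists became 0 with an estimated correlation, 1 with fry, 3 with the striatal covariate, both with 8 arrays and without BSKO 2, where the striatal list drops out by construction, and 5 to 11 when 1 array was left out (5 without BSKO 2, 11 without BSKO 4). Under that covariate, only the meningeal and astrocyte lists with 8 arrays, and only the heat shock list without BSKO 2, came from the 7. With the striatal covariate the monoaminergic neuron median turned to 0.066 with 8 arrays and 0.36 without BSKO 2, and the monoamine synthesis median to 0.030 and 0.10. Sirt1 stayed lower in all alternatives, from -0.86 to -0.15, and never passed. Over 27 named probe sets and 481 alternative values, 324 kept their side of the threshold, 54 lost it, 103 gained it and 0 changed sign. The dim-probe filter was not run, and signal over background is unknown for centred values.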

Other observations

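The test of chromosome segments was chosen after the called genes were seen, and the margin required between the real and the other splits was added after their counts were seen. The values by array were picked after they were seen.

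Transcripts of small brain regions and attached tissue differed between arrays of the same genotype, several of them between replicates 1 and 2 and replicates 3 and 4. The oxytocin gene Oxt was 3.42 and 2.99 on BSKO 1 and BSKO 2 and -2.22 to 0.19 on the other 6 arrays, and the galanin gene Gal was 2.75 and 2.50 on BSKO 1 and BSKO 2. The hypothalamic list had a median difference of 0.68 and did not pass (adjusted p = 0.0720, and adjusted p = 0.712 with an estimated correlation). The orexin gene Hcrt was -3.51 and -2.44 on BSKO 3 and BSKO 4 and 1.62 on BSKO 2. The growth hormone gene Gh (1460613_x_at) was 3.16 and 3.27 on WT 3 and WT 4, and the prolactin gene Prl was 2.06 and 2.07 there, but the median of the 9 pituitary genes was 0.0067 and 0.0083 on those WT arrays and highest on BSKO 2 (0.475). The choroid plexus list had a median of -1.92 on BSKO 4, where Kl (1423400_at) was -2.86 and Ttr (1451580_a_at) -1.31, against -0.15 to 0.50 for the list on the other arrays. The values of all tested probe sets correlated at 0.70 between WT 1 and WT 2 and at 0.472 between WT 3 and WT 4. The correlation was lower in BSKO, at 0.202 between BSKO 1 and BSKO 2 and 0.361 between BSKO 3 and BSKO 4. These are taken across probe sets, which are not independent replicates.

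Genes called without BSKO 2 often lay beside each other. Among 297 called genes, 30 were next to another called gene in the order of 12375 measured genes (RefSeq, assembly GRCm38.p6), where 10000 random gene lists gave a median of 14 and passed 23 in at most 5% of draws. The pairs include Nr2f2 with B130024G19Rik, Cav1 with Cav2, Dbp with Sphk2, and Itga4 with Neurod1. Chromosome segments that differ between the groups could give this, and so could co-expression of neighbours in any grouping of these arrays. With equally long lists ranked by p, 1 of the 35 splits, the real one, reached 30, but the split of replicates 3 and 4 against the rest had 29 and the median of the other splits was 17 (SD 6.48). A margin of 1 is within that spread, so the 2 explanations cannot be told apart here.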
